A study of Drosophila melanogaster with 12 samples.

How the data were processed

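Brains were dissected from 3-day-old female Drosophila melanogaster that expressed CAG0, CAG100 or CAA/G105 under elav-GAL4, with 4 samples of about 20 brains per genotype. Flies were kept at 25 °C in a light-dark cycle. Per the labels, total RNA was extracted, cDNA was amplified with the NuGEN Ovation Pico WTA system and labelled with biotin, and each sample was hybridised to 1 single-colour Affymetrix array. Per the submitters' processing notes the values were made with GCRMA, which corrects background by probe sequence and normalises across arrays, and with Partek, with no versions or settings given. The deposited values are log2 expression per probe set, not centred, and lay between 1.75 and 16.0 on every array. They were used as deposited. The number of arrays, 4 per genotype, limits the precision, and no measure of depth applies.

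The table held 18952 probe sets, of which 183 are Affymetrix controls, 13647 name 1 gene, 402 name several and 4720 name none. Gene symbols came from the array's annotation, with 13544 of the single-gene probe sets matched to a gene table of assembly Release 6 plus ISO1 MT, used only for names and the order of genes along chromosome arms. No genome build was given for the arrays, so no coordinates are reported. A probe set was tested if it reached log2 4 on at least 4 of the 12 arrays, which kept 8966 probe sets for 6969 genes and left out 9803.

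One linear model with 3 genotype means over all 12 arrays was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend on the mean. Each comparison was adjusted by the Benjamini-Hochberg method over the tested probe sets, with a threshold of adjusted p under 0.05 and no fold change minimum. For gene lists 1 probe set per gene was used, the one with the highest mean. Lists with at least 5 measured genes were tested with limma's camera at its preset correlation of 0.01 and adjusted over the lists. Members were also adjusted over their list alone.

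Genes were named by a rule. For each comparison it took the 10 largest increases and 10 largest decreases among probe sets that passed, named 1 gene and had no overlap between the arrays of the genotypes. It took the same for probe sets that CAG100 changed against both others, up to 4 members of each gene list with the largest change, or the 2 with the smallest p where none passed, and always w, elav, roX1 and the Hsp70 genes. No probe set is named for w or roX1, and Hsp70 appears only in 5 probe sets that name several genes, so these are not reported, and the transgene copy number was not checked against a marker. Among the genes the rule named, those given as examples were mostly ones that kept their result under the alternatives, and this choice was made after the values were seen. Of 248 results of named genes that passed, 153 kept their call under every alternative. CG14075, RFeSP, Nlg4 and Cyp6a19 lie outside the rule and were chosen after their values were seen.

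The gene lists covered heat shock proteins and chaperones, the unfolded protein response, splicing and RNA binding, small RNA pathways, immune induction, glutathione and oxidative stress, cytochrome P450, synaptic transmission, neuropeptides, oxidative phosphorylation, proteasome and ubiquitin, autophagy, apoptosis and JNK signalling, ribosomal proteins, the circadian clock, histones, ecdysone and juvenile hormone, activity-regulated genes, and the transgene and driver. For other tissue that could adhere to a brain they covered glia, photoreceptors, fat body, muscle, haemocytes, olfactory appendages, retrocerebral gland, cuticle and trachea, and male-specific transcripts. Samples, comparisons, tests, thresholds, gene lists, the naming rule and most alternatives were fixed before the data were examined. A restriction to probe sets measured in all genotypes, leaving out the 3 arrays without Akh signal, and marker scores as covariates were added after seeing the data.

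Alternatives covered the filter, the scaling, the variance model, array weights, the arrays in the fit, a block on replicate number, the threshold, the probe set of a gene, the list test and leaving out each array in turn. The overlap of both repeats was set beside 100 simulations of unchanged groups with shared controls and beside all 6 splits of the control arrays. Counts were recomputed for other splits of the arrays between genotypes. RNA quality was compared with exact permutation tests on the array's control probe sets. The pipeline was tested on simulated data with the arrays' own spread, with 200 of 8966 probe sets changed in each of 10 simulations. It recovered 71.2%, 91.8% and 97.9% of changes of log2 0.50, 1.00 and 2.00, and 3.92% of its calls were false. Among the tests of explanations, the correlation of arrays within genotypes replaced the share of probe sets reaching log2 4, which the normalization nearly fixes, and the median change of marker genes replaced correlations of list means, which decided nothing. Both were changed after the earlier results and the values now used had been seen.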

Results

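Messenger RNA was measured on 12 Affymetrix arrays in brains of 3-day-old female flies in which the elav-GAL4 driver, active in neurons, switched on a DsRed reporter. The reporter carried no repeat behind its coding sequence (CAG0), 100 CAG units (CAG100) or a run of similar length in which CAA units interrupt the CAG (CAA/G105). The series text calls the pure repeat toxic and the interrupted one non-toxic, and gives 1, 5 and 2 transgene copies for CAG0, CAG100 and CAA/G105, set so that the reporter mRNA matched. Each genotype had 4 arrays, each from about 20 brains with the eyes, lamina and outer medulla taken off. The labels call the 4 independent, so p-values measure spread between samples, and the number of arrays limits the precision. Values are deposited log2 signals, levels are given ± SD over 4 arrays, and differences are given ± SE from limma.

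Arrays of 1 genotype correlated at r = 0.9957 to 0.9986 and arrays of different genotypes at r = 0.9929 to 0.996. Between 47.1% and 47.5% of probe sets reached log2 4 on each array. The elav transcript, whose promoter the driver uses, was 13.69 ± 0.03 in CAG100, 13.73 ± 0.05 in CAA/G105 and 13.77 ± 0.08 in CAG0, with no comparison past the test (adjusted p = 0.159 to 0.574). Where a genotype lay under log2 4 on all its arrays, a fold change is given as "at least", computed against log2 4. Akh, the adipokinetic hormone gene of a gland attached to the brain, read 2.25 and 2.43 on CAG100 replicates 1 and 3 and 2.06 on CAA/G105 replicate 3, and at least 11.04 on the other 9 arrays.

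**Figure D1:**
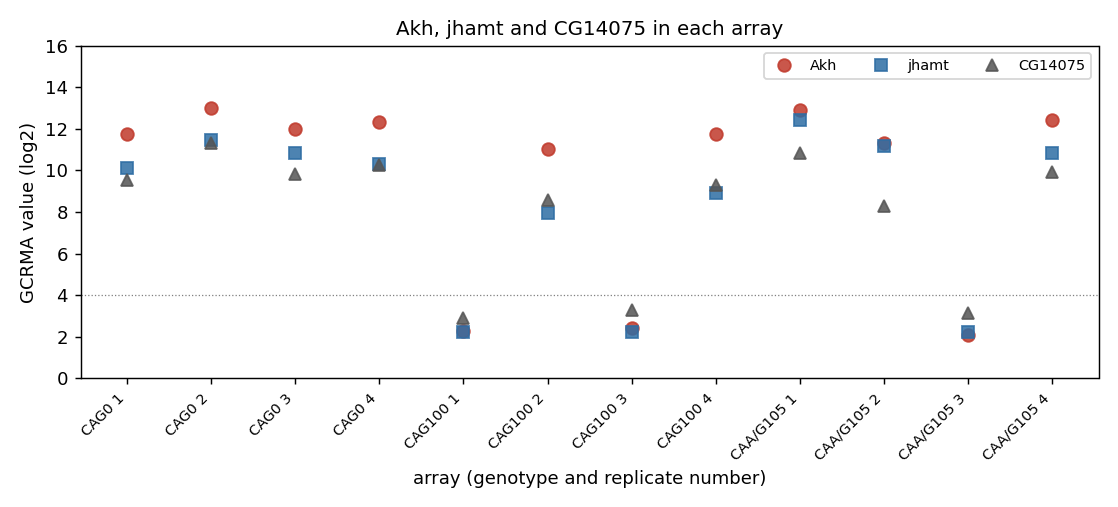
Log2 signal (vertical axis) of Akh, jhamt and CG14075 on each of the 12 arrays, by genotype and replicate; each point is an array. All 3 genes were near background on the same 3 arrays.

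The first question of the series text was which genes respond to the toxic repeat, in CAG100 against CAG0. The cytochrome P450 gene Cyp6a17 read 12.50 ± 0.21 in CAG100 and 2.08 ± 0.01 in CAG0 (at least 361-fold, adjusted p = 0.000101). KaiR1D, a kainate-type glutamate receptor subunit, fell from 12.08 ± 0.04 to 3.32 ± 0.03 (at least 270-fold, adjusted p = 2.62e-17). Neither Cyp6a17 nor KaiR1D had another measured probe set. The methuselah-like receptor gene mthl8 fell at least 89.6-fold, from 10.48 ± 0.37 to 2.13 ± 0.01. The antimicrobial peptide gene Mtk rose 9.43-fold, by 3.24 ± 0.58 (adjusted p = 0.00234).

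In all, 705 probe sets were higher and 934 lower, which is 18.3% of the 8966 tested. Most changes were small: 593 of the 1639 reached 1.5-fold and 286 reached 2-fold. With every array shifted to the same median the split was 877 higher and 751 lower, so the balance of the directions depends on scaling. Without the 3 arrays that lacked the signal of the gland hormone gene Akh, 2 of them CAG100, 948 probe sets passed, with fewer arrays to test. With scores of muscle, fat body and gland genes as covariates 1040 passed. Among the largest increases were the UDP-glycosyltransferase gene Ugt35C1 (39.6-fold), tyn, which encodes a zona pellucida domain protein (22.9-fold), and fzy, an activator of the anaphase-promoting complex (at least 6.8-fold). Among the largest decreases were Kmn1, a kinetochore gene (25.1-fold, a difference of -4.65 ± 0.08), the transcription factor gene NFAT (13.8-fold, -3.79 ± 0.15) and CG13284 (at least 50.7-fold).

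**Figure D2:**
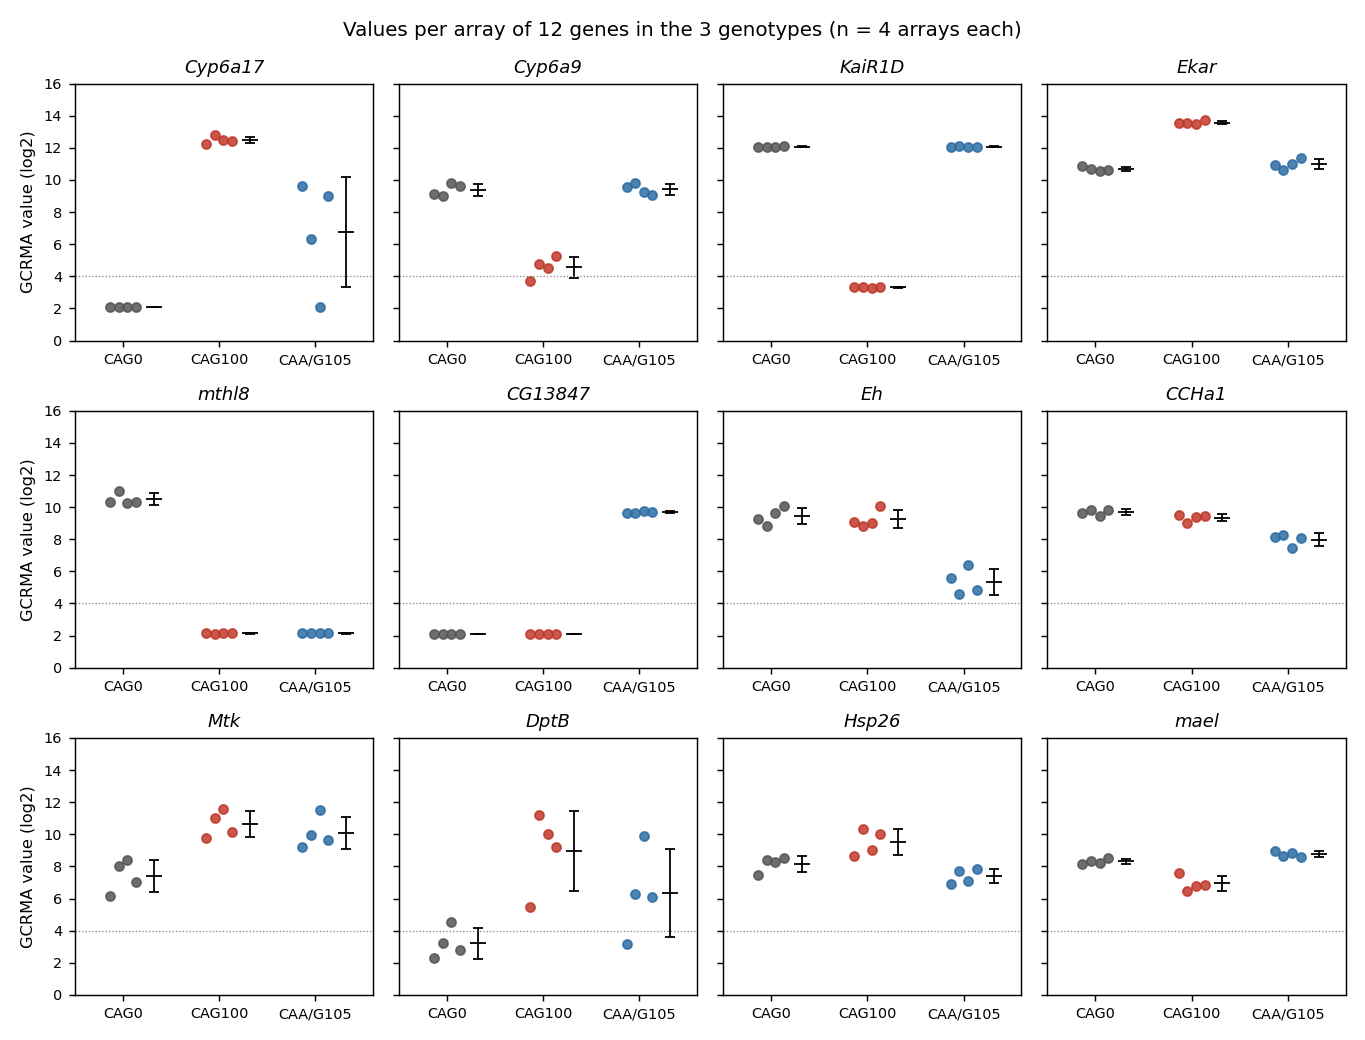
Log2 signal (vertical axis) of 12 genes on each array, by genotype; points are arrays, bars are the mean ± SD of 4 arrays and the dotted line is log2 4. Cyp6a17, KaiR1D, mthl8 and CG13847 went from below the line in all arrays of at least 1 genotype to far above it in another.

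Of 42 measured cytochrome P450 genes 7 were higher and 8 lower, and 10 and 14 when adjusted over the list alone; the list as a whole did not pass (adjusted p = 0.779). The changes included neighbours of Cyp6a17 on chromosome arm 2R: Cyp6a9 fell 28.2-fold (-4.82 ± 0.30), Cyp6a20 fell 10.8-fold and Cyp6a23 fell 9.93-fold. Antimicrobial and immune-induced genes had 5 of 14 members higher and 1 lower (6 and 2 over the list alone), and the list fell just short of the threshold (adjusted p = 0.0541). Besides Mtk they included DptB, another antimicrobial peptide gene (8.97 ± 2.48 against 3.21 ± 0.97, adjusted p = 0.0114), and BomS2, an immune-induced peptide gene (1.69 ± 0.33 higher, adjusted p = 0.00374). With those scores as covariates DptB and BomS2 missed the threshold (adjusted p = 0.0782 and 0.0503, over ranges of 0.00131 to 0.0782 for DptB and 0.000529 to 0.0503 for BomS2 across alternatives). In the same comparison 3 of 17 fat body and haemolymph genes were higher and none lower (4 and 1 over the list alone), and that list passed (adjusted p = 0.0298, but adjusted p = 0.912 with an estimated correlation). Its result was also lost without CAG0 replicate 2 (adjusted p = 0.156) or 4 (0.119), without CAG100 replicate 1 (0.0531) or 3 (0.0695), after both rescalings (0.0777 and 0.0521) and without the 3 arrays that lacked Akh signal (0.204), over a range of 0.000316 to 0.204 across alternatives that kept the list test unchanged. None of 16 haemocyte genes passed.

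Cytosolic ribosomal protein genes rose as a list, with 11 of 29 higher and none lower (19 and 0 over the list alone, adjusted p = 1.43e-09), and so did oxidative phosphorylation genes, with 6 of 54 higher (4 over the list alone, adjusted p = 6.82e-07). Both results were lost when the correlation between genes was estimated from the data (adjusted p = 0.912 with an estimated correlation for each). With another list test of limma, fry, ribosomal protein genes passed (adjusted p = 0.00939) and oxidative phosphorylation genes did not (0.131). Their changes were slight: RpL27 rose 1.41-fold, RpL32 1.09-fold, and the complex II subunit gene SdhD 1.23-fold. Synaptic transmission genes fell as a list, with 10 of 46 lower and none higher (12 and 0 over the list alone, adjusted p = 0.000601, and adjusted p = 0.912 with an estimated correlation). They included the dopamine transporter gene DAT (-0.53 ± 0.06), the glutamate receptor gene Nmdar1 (-0.37 ± 0.05) and the acetylcholine receptor genes nAChRalpha5 (-0.39 ± 0.09) and nAChRalpha7 (-0.36 ± 0.08).

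Neuropeptide genes went both ways, with 4 of 32 higher and 6 lower (5 and 6 over the list alone, adjusted p = 0.985; the test pointed up, the median was -0.02). The list contains Akh, and its mean was 11.73 and 11.71 on the CAG100 arrays that lacked Akh signal against 11.99 and 12.11 on the other CAG100 arrays. FMRFa fell 1.66-fold (-0.73 ± 0.13) and SIFa rose 1.47-fold (0.56 ± 0.09). Small RNA pathway genes had 7 of 17 members lower and 1 higher, over the list alone as well (adjusted p = 0.291 for the list), with mael, a gene of the piRNA pathway, down 2.58-fold (-1.37 ± 0.20). Glutathione and oxidative stress genes had 6 of 27 higher and 2 lower (8 and 2 over the list alone, adjusted p = 0.0601): GstE2 rose 1.53-fold and GstD1 fell 1.40-fold. Autophagy genes had 5 of 27 lower and none higher, over the list alone as well (adjusted p = 0.13), with the protease gene Atg4a down 1.35-fold. Heat shock proteins and chaperones had 1 of 24 higher and 2 lower (adjusted p = 0.873, where the test pointed up and the mean was -0.015). Small heat shock protein genes went both ways. Hsp27 fell 2.34-fold, while Hsp26 was the higher gene, at 8.64 to 10.36 per array in CAG100 and 7.46 to 8.53 in CAG0. The Hsp26 call did not hold under every alternative (limma adjusted p = 0.00073 to 0.0727). Only 2 of 29 proteasome and ubiquitin genes changed, both higher (1 over the list alone, adjusted p = 0.362), with Prosbeta4 up 1.37-fold.

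The interrupted repeat, CAA/G105 against CAG0, was the comparison by which the series text meant to exclude responses to a non-toxic repeat. CG13847 read 9.68 ± 0.05 in CAA/G105 and 2.11 ± 0.01 in CAG0 (at least 51.4-fold, adjusted p = 8.87e-15). The eclosion hormone gene Eh fell 17.1-fold, from 9.44 ± 0.52 to 5.34 ± 0.81 (adjusted p = 1.96e-05). Ugt35C1 rose 65.1-fold (6.02 ± 0.14), and mthl8 fell at least 89.6-fold here too. The peroxiredoxin gene Prx6c rose from 3.10 ± 1.08 to 8.76 ± 1.98 and the cytochrome P450 gene Cyp4p2 from 3.74 ± 1.21 to 9.29 ± 0.14, both from a CAG0 level that lay under log2 4 on 3 of 4 arrays.

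The test passed 492 probe sets that were higher and 692 that were lower, 13.2% of those tested, of which 502 reached 1.5-fold. As in CAG100 against CAG0, the balance of the directions may depend on scaling. Neuropeptide genes fell as a list: 11 of 32 were lower and none higher (12 and 1 over the list alone, adjusted p = 0.00184; adjusted p = 0.997 with an estimated correlation). The list mean was 11.45 on CAA/G105 replicate 3, which lacked Akh signal, and 11.67 to 11.81 on the other CAA/G105 arrays. The lower genes included CCHa1 (-1.70 ± 0.18), the leucokinin gene Lk (-1.36 ± 0.15) and the insulin-like peptide gene Ilp5 (-0.94 ± 0.08). Haemocyte genes fell as a list, with 4 of 16 lower (6 over the list alone, adjusted p = 0.0141, and adjusted p = 0.997 with an estimated correlation), among them SPARC, a basement membrane protein gene (-0.40 ± 0.07). The haemocyte mean was 10.30 on CAG0 replicate 1 against 9.63 to 9.84 on the other CAG0 arrays, and 8.98 on CAA/G105 replicate 3 against 9.51 to 9.64. Without CAG0 replicate 1 the haemocyte list missed the threshold (adjusted p = 0.0785, over a range of 0.000179 to 0.0785 across alternatives that kept the list test unchanged). Ribosomal protein genes rose, with 3 of 29 higher (3 over the list alone, adjusted p = 0.0336, and adjusted p = 0.997 with an estimated correlation), among them RpL27 (1.32-fold). That result was lost without CAG0 replicate 1 (adjusted p = 0.115) or CAA/G105 replicate 1 (0.322), over a range of 0.00219 to 0.322 across alternatives that kept the list test unchanged. It was lost as well with no filter on low values (adjusted p = 0.125), with quantile normalization (0.209) and with a variance model without trend (0.131).

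Of the cytochrome P450 genes 6 were higher and 5 lower (7 and 6 over the list alone, adjusted p = 0.673), with Cyp4p1 up 4.91-fold and Cyp9b1 up 3.58-fold. Glutathione genes had 5 higher and 1 lower (6 and 2 over the list alone, adjusted p = 0.0526): GstE2 rose 1.41-fold and GstE9 fell 7.51-fold (-2.91 ± 0.48). Immune genes had 3 of 14 higher and 1 lower (4 and 1 over the list alone, adjusted p = 0.164). Mtk rose 6.38-fold (2.67 ± 0.58) and dl, a transcription factor of the Toll pathway, fell 1.32-fold. Hen1, a small RNA methyltransferase gene, rose 3.37-fold (1.75 ± 0.22). Of 54 oxidative phosphorylation genes 2 were higher and 4 lower (adjusted p = 0.673), with UQCR-11, a complex III subunit gene, down 3.54-fold. Only 2 of 46 synaptic genes changed, both lower, and none over the list alone. The flight muscle gene fln, which encodes flightin, fell 3.88-fold (-1.96 ± 0.11).

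**Figure D3:**
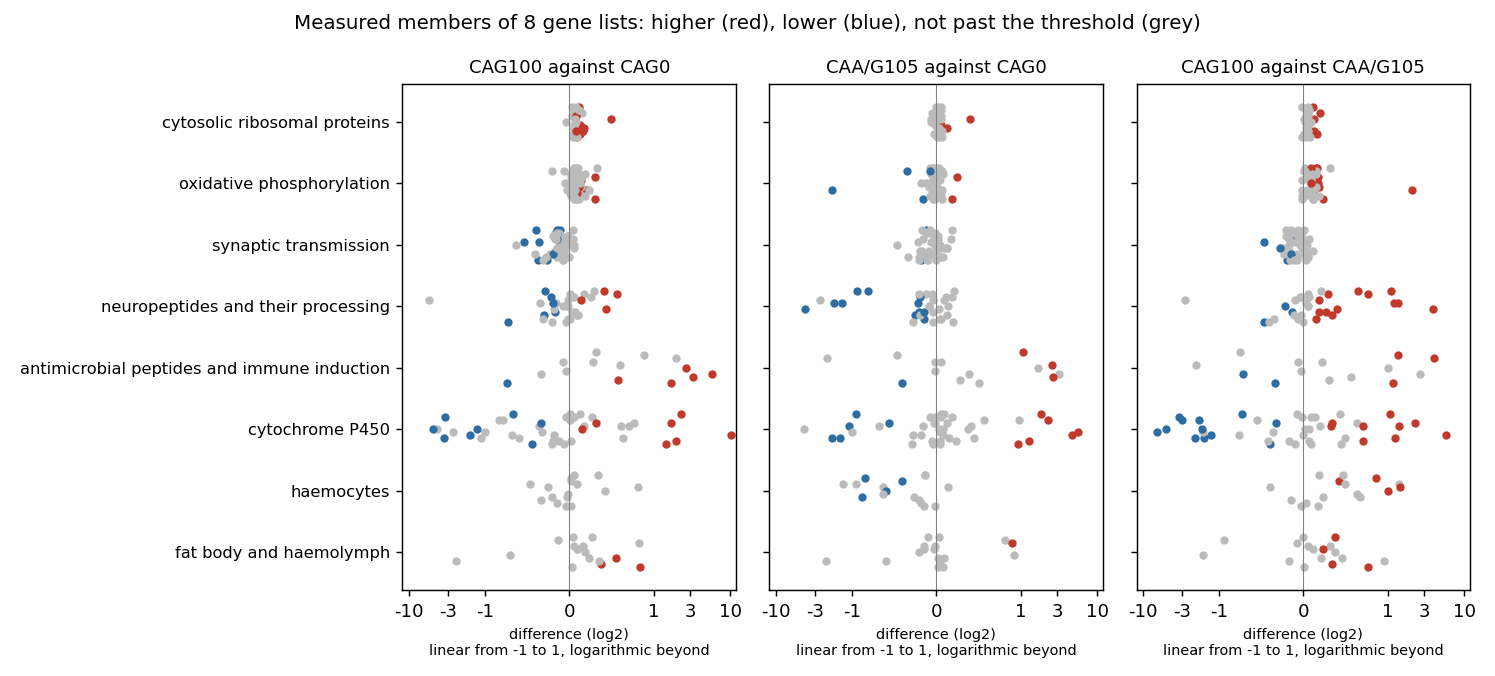
Log2 fold change (horizontal axis, linear near 0 and logarithmic outside) of the members of 8 gene lists (vertical axis) in the 3 comparisons. Each point is a gene, coloured by whether it passed the test. In CAA/G105 against CAG0, 11 of 32 neuropeptide genes passed as lower and none as higher (the list had adjusted p = 0.997 with an estimated correlation), and ribosomal protein genes lay close to 0.

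A direct comparison of both repeats, CAG100 against CAA/G105, had 930 probe sets higher and 939 lower in CAG100 (20.8%), and 924 in all without the 3 arrays that lacked Akh signal. KaiR1D was at least 267-fold lower in CAG100 and CG13847 at least 51.4-fold lower. Cyp4p2 was at least 39.2-fold lower and Cyp6a9 28.9-fold lower (-4.85 ± 0.30). Eh was 15.1-fold higher (3.91 ± 0.40) and GstE9 18.7-fold higher (4.23 ± 0.48). Hsp26, a small heat shock protein gene, was 4.37-fold higher (9.52 ± 0.81 against 7.39 ± 0.45, adjusted p = 0.00161).

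Neuropeptide genes were higher in CAG100 as a list, with 13 of 32 higher and 3 lower (13 and 4 over the list alone, adjusted p = 0.00645, and adjusted p = 0.885 with an estimated correlation). Akh, a member, lacked signal on 2 CAG100 arrays and 1 CAA/G105 array. CCHa1 (1.35 ± 0.18), Lk (1.20 ± 0.15) and the cardioactive peptide gene CCAP (1.10 ± 0.12) were among the higher ones. Oxidative phosphorylation genes were higher too, with 15 of 54 higher and none lower (20 and 0 over the list alone, adjusted p = 1.14e-07, and adjusted p = 0.885 with an estimated correlation). ATPsynB was 1.17-fold and UQCR-11 4.15-fold higher. Ribosomal protein genes had 6 of 29 higher (6 over the list alone, adjusted p = 0.000481), proteasome genes 5 of 29 (5 over the list alone, adjusted p = 0.0211), and synaptic genes 5 of 46 lower (2 over the list alone, adjusted p = 0.0245), DAT among them (-0.47 ± 0.06). These 3 results were lost too (adjusted p = 0.885 with an estimated correlation for each). Leaving out an array ended the synaptic result for CAG100 replicate 3 (adjusted p = 0.205) or 4 (0.053) and CAA/G105 replicate 3 (0.133), and so did leaving out the 3 arrays that lacked Akh signal (0.0522), over a range of 0.000991 to 0.205 across alternatives that kept the list test unchanged. It ended the proteasome result for CAG100 replicate 3 (adjusted p = 0.066) and CAA/G105 replicate 2 (0.0775) or 3 (0.053), over a range of 0.000131 to 0.0775 across alternatives that kept the list test unchanged. Lists of other cell types were higher as well: haemocyte genes had 4 of 16 higher (4 over the list alone, adjusted p = 0.0126), with the prophenoloxidase gene PPO2 2.02-fold up, and fat body genes 4 of 17 higher (6 over the list alone, adjusted p = 0.0416). Both were lost likewise (adjusted p = 0.885 with an estimated correlation for each). The fat body result also ended without CAG100 replicate 1 (adjusted p = 0.0818) or 3 (0.0936) and without CAA/G105 replicate 3 (0.111) or 4 (0.0516), over a range of 0.0157 to 0.325 across alternatives that kept the list test unchanged. Quantile normalization (adjusted p = 0.0578), array weights (0.0531) and leaving out the 3 arrays that lacked Akh signal (0.325) ended it too.

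Small RNA genes had 4 of 17 lower and none higher (4 and 1 over the list alone, adjusted p = 0.0958), with mael 3.52-fold lower (-1.81 ± 0.20). Autophagy genes had 5 of 27 lower (adjusted p = 0.139), with Atg18b 2.34-fold lower. Cytochrome P450 genes had 9 higher and 12 lower (10 and 14 over the list alone, adjusted p = 0.719). Immune genes had 3 higher and 2 lower (3 and 3 over the list alone, adjusted p = 0.745), with spz, the Toll ligand gene, 1.64-fold lower. Glutathione genes had 3 higher and 5 lower, with GstD1 1.86-fold lower (-0.89 ± 0.08).

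Following the exclusion that the series text describes, 1129 probe sets changed in CAG100 against CAG0 and not in CAA/G105 against CAG0, 486 higher and 643 lower (610 and 499 with the arrays shifted to the same median). The count was 715 without CAG100 replicate 2, 629 without the 3 arrays that lacked Akh signal, and 656 with the covariates. Missing the test in CAA/G105 does not show a difference between the repeats: 667 of the 1129 also differed the same way between CAG100 and CAA/G105, and 462 did not. Counting any probe set that differed the same way in CAG100 against both others gave 806, with 381 higher and 425 lower, a balance that may depend on scaling too. This count was 532 without CAG100 replicate 2 and 421 without the 3 arrays that lacked Akh signal. KaiR1D, Cyp6a9, CG13428 (at least 20.3-fold higher against each), fzy, Cyp6a17 and mael belong to the 806. Cyp6a17 was also called higher in CAA/G105 than in CAG0 (adjusted p = 0.0235), at 9.61, 6.32 and 9.02 on replicates 1, 2 and 4 and 2.09 on replicate 3. All CAG0 arrays read 2.07 to 2.1, under log2 4, so no exact size of the difference is given. That call was lost without CAA/G105 replicate 1 (adjusted p = 0.0582) or 4 (0.0686) and without CAG0 replicate 1 (0.0503), 2 (0.0562) or 4 (0.0558), over a range of 3.02e-05 to 0.0695 across alternatives.

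Both repeat genotypes differed from CAG0 the same way in 434 probe sets, 183 higher and 251 lower, where 38.7 and 72.1 would be expected if the lists were independent. The comparisons share their control arrays, so independence is not the right expectation. Since CAG0 is their only control genotype, a trait of CAG0 itself cannot be told apart from a change in both repeat genotypes. Another 76 went opposite ways. Of the 434, 322 did not pass the test of CAG100 against CAA/G105, among them Kmn1, which read 7.30 ± 0.11 in CAG100 and 7.40 ± 0.13 in CAA/G105. The genes mthl8, CG43117 (at least 15.6-fold lower in both) and Reepl1 (at least 6.71-fold lower in both) lay under log2 4 on every array of both repeats, where levels cannot be compared.

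Fold changes of CAG100 and of CAA/G105 against CAG0 correlated at r = 0.43 (jackknife SE 0.043, Spearman 0.322), while unchanged groups with shared controls gave r = 0.496 in 100 simulations. The covariance was 0.115 against 0.0164 simulated. With the 4 control arrays split between the comparisons in each of the 6 possible ways, r ran from 0.328 to 0.38 and the covariance from 0.0939 to 0.105. No control array served both comparisons in these splits, so noise of shared arrays cannot give these values, while a trait common to all CAG0 arrays still could. Signs matched in 61.4% of probe sets against 66.7% simulated.

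**Figure D4:**
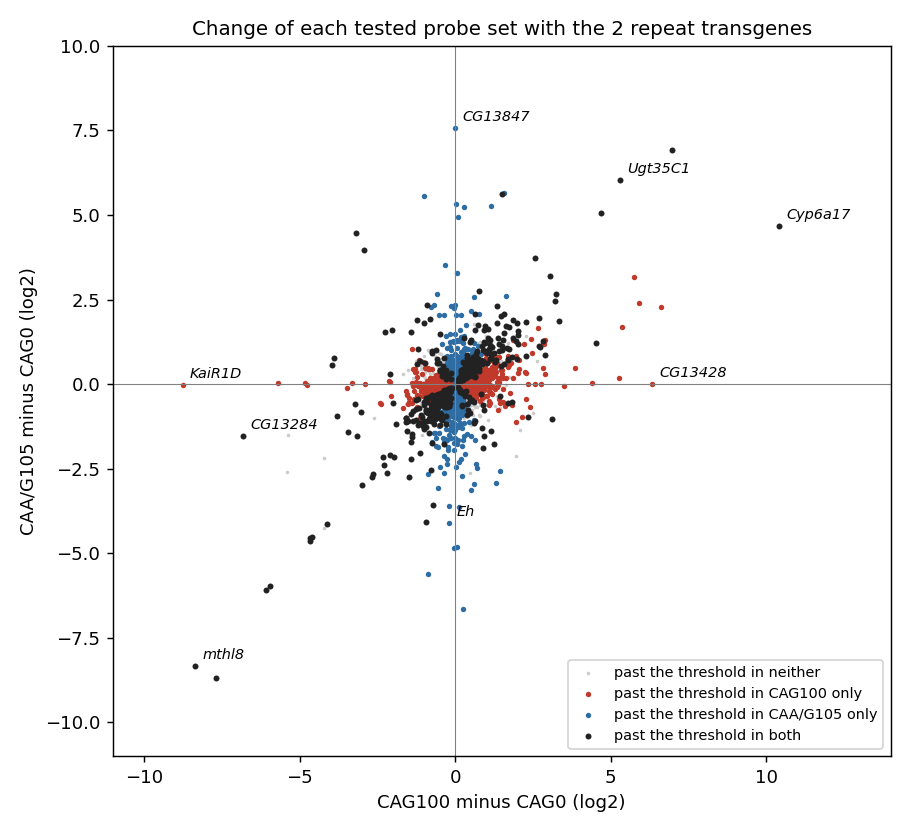
Log2 fold change of CAG100 against CAG0 (horizontal axis) and of CAA/G105 against CAG0 (vertical axis); each point is a probe set, coloured by the comparisons in which it passed the test. Points along an axis differed from CAG0 mainly with 1 of the repeats, and genes at background in both repeats, such as mthl8, lie on the diagonal for that reason.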

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

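The tests of single probe sets, of immune genes and of the missing gland genes were chosen only after their results were seen, and the tests of neighbouring genes before. Of 284 groups of 4 arrays tested for a single array far from the others, among 72 genes, 23 list scores and the array's quality controls, 19 had one, where chance flags about 1 in 20 groups, or 14.2. Each is given with the gap to the nearest array over the range of the 4.

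Akh, made by the corpora cardiaca, read 2.06 on CAA/G105 replicate 3 against 11.32 to 12.92 on the others (0.853), jhamt, a juvenile hormone enzyme of the corpora allata, read 2.22 against 10.86 to 12.43 (0.847), and the mean of retrocerebral gland genes read 5.96 against 9.06 to 9.53 (0.869). Both genes also lay under log2 4 on CAG100 replicates 1 and 3, as did CG14075, while no probe set was missing in this way from any other set of 3 arrays out of 220. A failed hybridisation of these arrays is argued against by their mean correlation with the other arrays of their genotype. It was 0.99722 or more (lowest on CAA/G105 replicate 3), inside the range of the other 9 (0.99695 to 0.99832). CAA/G105 replicate 3 and CAG100 replicate 1 (0.99764) lay at the low end of that range. Of the other 9, only CAA/G105 replicate 1, which had Akh signal, lay below them. Silencing of these genes by a repeat in all flies of a genotype is argued against, since other pools of the same genotypes kept them. On CAG100 replicates 2 and 4 Akh read 11.04 and 11.74 and jhamt 7.95 and 8.91. On the other CAA/G105 arrays both read 10.86 or more. Loss of the gland complex in dissection and an effect of the repeats on only some samples cannot be told apart. The match of jhamt with Akh in the same 3 of 12 arrays (exact probability 0.00455) is the pattern itself and supports neither.

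Several of the largest changes went from background to a high level, and the changes clustered along chromosomes, as for Cyp6a17, Cyp6a23, Cyp6a19, Cyp6a9 and Cyp6a20, consecutive on arm 2R in the gene table, where in CAG100 against CAG0 Cyp6a17 rose and the other 4 fell (Cyp6a19 by 0.67, adjusted p = 0.0145). Genes 6 to 50 places apart changed the same way more often than with shuffled positions in all 3 comparisons (ratios 1.06, 1.07 and 1.02, permutation p = 0.001, 0.001 and 0.04). This argues against tandem copies of related genes within 5 places as the whole cause (highest ratio 1.07). Wider clusters of related genes were not tested. The excess was larger 1 to 5 places apart (1.22, 1.16 and 1.14), where tandem copies may contribute. At 51 to 200 places apart it was 1.02, 1.06 and 1.02 (permutation p = 0.09, 0.001 and 0.05). Stretches of different genetic background in the stocks may contribute, since the excess they require was there (lowest ratio 1.02), and the design confounds them with genotype. Whether single probe sets and not the transcript changed cannot be told apart. Only 41 of 216 changes of at least 4-fold had another measured probe set of the gene, and KaiR1D, Cyp6a17 and CG13847 had none. Of 19 genes with such a change and another measured probe set, 8 had most of the others changed the same way (42.1%, exact 95% interval 20.3 to 66.5). It was so in mthl8 and not in RFeSP (3.20 against 0.10) or Nlg4 (-2.25 against 0.09). Transgene copies also differed with genotype (1 in CAG0, 5 in CAG100 and 2 in CAA/G105). A response to the repeats was not separated from background or from the transgene copies and stays open.

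In CAG100 against CAG0, 5 of 14 immune genes were higher, Mtk and DptB among them, and 1 lower, while the list as a whole did not pass (adjusted p = 0.0541, and 0.912 with an estimated correlation). Its mean was 9.15 to 10.07 per array in CAG100, 8.12 to 9.03 in CAG0 and 8.93 to 9.72 in CAA/G105. The 5 higher immune genes rose by a median of 2.66, but they were picked by that same test, and all 14 had a median of 0.591. More haemocyte RNA as the whole cause is argued against, since the median change of 16 haemocyte genes was 0.007 (SD 0.31). More fat body or haemolymph RNA stays open. The median of its 17 genes, 0.163 (SD 0.71), lay within that SD of the median of all 14, and the fat body list had passed its test. Within genotypes the immune mean correlated with the fat body mean at r = -0.033 and with the haemocyte mean at r = -0.138 over 12 arrays (permutation p = 0.932 and 0.676), which decides nothing. Different exposure to microbes between stocks or a response to the repeat could also raise these genes, and neither was tested.

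Replicate 1 of CAG100 stood apart in Cyp6a23 (5.83 against 6.90 to 7.06, 0.871), egr (11.42 against 11.70 to 11.75, 0.84), GstD1 (12.72 against 13.10 to 13.16, 0.872), Nlg4 (8.46 against 8.27 to 8.29, 0.879) and Prosbeta4 (11.78 against 11.93 to 11.95, 0.917). CAG0 replicate 1 stood apart in Cyp4p2 (5.56 against 3.08 to 3.18, 0.96), Prx6c (4.71 against 2.50 to 2.64, 0.935) and drpr (13.28 against 13.19 to 13.20, 0.855). CAG0 replicate 3 stood apart in inaE (12.29 against 12.73 to 12.78, 0.895) and tyn (5.78 against 6.32 to 6.42, 0.84), and CAG0 replicate 2 in mthl8 (11.03 against 10.25 to 10.34, 0.883). CAA/G105 replicate 2 stood apart in Prx6c (5.82 against 9.35 to 10.07, 0.831), spz (9.50 against 9.83 to 9.85, 0.946) and Cyp6a19 (5.74 against 5.18 to 5.25, 0.863), replicate 4 in DAT (10.96 against 11.04 to 11.05, 0.903), and replicate 1 in the mean of small RNA pathway genes (10.59 against 10.63 to 10.64, 0.849).

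A signal appeared in data that no comparison used: 1 of the array's control probe sets for a foreign sequence had a mean of 8.55 over the 12 arrays (8.05 to 8.89), while the other 99 of its kind had a median of 2.17 and only 1 of them reached log2 4. It was 8.68 ± 0.12 in CAG0, 8.39 ± 0.30 in CAG100 and 8.57 ± 0.24 in CAA/G105 (exact permutation p = 0.171 and 0.457 against CAG0, and 0.4 between the repeats). Its name refers to a sequence record, but the sources used here do not say what that sequence is.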

How the results depend on the processing

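The restriction to probe sets measured in all genotypes, the left-out arrays without Akh signal and the marker covariates were chosen after the results were seen. Counts stayed within 1.5 times of their value, and the correlation within its jackknife SE, except as follows, and no result of a named gene reversed. Requiring 1.5-fold left 593, 502 and 701 probe sets in CAG100 against CAG0, CAA/G105 against CAG0 and CAG100 against CAA/G105, with 390 for the exclusion list and 290 against both others; unadjusted p with 1.5-fold gave 698, 596, 793, 431 and 357. Without the 3 arrays lacking Akh signal the counts were 948, 855, 924, 629 and 421, with fewer arrays to test. Marker scores as covariates gave 1040 in CAG100 against CAG0 and 656 for the exclusion list, and the cause was not tested. Measured in all 3 genotypes, fold changes correlated at r = 0.371, a set without most on or off genes. Leaving out each array gave 1119 to 1949, 874 to 1529, 1353 to 2156, 715 to 1266 and 532 to 970, and r = 0.41 to 0.458. Gene lists that passed were 3 to 6, 1 to 4 and 4 to 7 when each array was left out. An estimated correlation left 0, 0 and 0 lists, with adjusted p of 0.885 or more for every list, so it did not separate the lists. The list test fry left 1, 1 and 1. These were ribosomal protein genes in CAG100 against CAG0 (fry adjusted p = 0.00939) and neuropeptide genes in CAA/G105 against CAG0 (0.00182) and CAG100 against CAA/G105 (0.00535). In CAA/G105 against CAG0, array weights, a replicate block and the 3 left-out arrays each gave 5 lists instead of 3, and the cause was not tested. The replicate block gave 1466, 1090, 1730, 987 and 722 probe sets and kept 230 of 248 named-gene results. Replicate numbers correlated at -0.259 to 0.39 across genotypes, with 3 of 12 pairs above 0.1, and 5 of 12 arrays correlated best with an array of their number, a hint from the data only. Of 248 named-gene results that passed, 178 kept their call with each array left out and 70 lost it with at least 1. Lists were not tested without moderation or with covariates, and the w transcript could not be computed. Signal near background limits genes under log2 4.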

Other observations

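The tests of other splits of the arrays were chosen before their results were seen, and the shares per chromosome arm after. Activity-regulated genes had 3 of 13 members higher and none lower in CAA/G105 against CAG0 (adjusted p = 0.346 for the list), among them sr, a transcription factor gene of the EGR family (0.73 ± 0.17, adjusted p = 0.0131) and Arc1 (0.31 ± 0.07), and in CAG100 against CAA/G105 2 were lower, with sr 2.46-fold lower (-1.30 ± 0.17). Against CAG0, 1 was higher and 1 lower in CAG100. Of 16 apoptosis and JNK genes 1 changed in each comparison that involved CAA/G105: egr, the fly TNF gene, was lower than in CAG0 (-0.32 ± 0.07) and higher in CAG100 than in CAA/G105 (0.53 ± 0.07), with none past the test in CAG100 against CAG0. Glial genes had 1 of 21 higher and 2 lower in CAG100 against CAG0 (adjusted p = 0.513), drpr (-0.24 ± 0.03) and the astrocyte gene alrm (-0.19 ± 0.03) being the lower ones. Glial genes had 3 higher and 1 lower in CAA/G105 against CAG0, and 3 higher and 2 lower in CAG100 against CAA/G105. Photoreceptor genes had 4, 1 and 2 of 20 lower in CAG100 against CAG0, CAA/G105 against CAG0 and CAG100 against CAA/G105, and none higher (adjusted p = 0.362, 0.236 and 0.848). The lipase gene inaE was lower in both repeats than in CAG0, by 1.38-fold and 1.33-fold.

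Splicing genes had 1 of 39 higher and 3 lower, 0 and 2, and 2 and 2 in the comparisons in that order, with Hrb87F lower in CAA/G105 than in CAG0 (-0.23 ± 0.05) and higher in CAG100 than in CAA/G105 (0.28 ± 0.05). Of 24 heat shock and chaperone genes, the chaperonin gene CCT7 alone rose in CAA/G105 against CAG0 (0.59 ± 0.11), and 1 was higher and 3 lower in CAG100 against CAA/G105. Unfolded protein response genes had 0 of 16 higher and 1 lower in CAG100 against CAG0, none in CAA/G105 against CAG0, and 1 each way in CAG100 against CAA/G105. Of 12 clock genes, 1 was higher and 1 lower in CAG100 against CAG0, and 2 were lower in CAG100 against CAA/G105, dco among them (-0.22 ± 0.04). In CAA/G105 against CAG0, autophagy genes had 1 higher, Atg18b (1.29 ± 0.09), and 3 lower, proteasome genes 1 each way, small RNA genes 1 higher and fat body genes 1 higher, which was lost over the list alone. Muscle genes had 0 of 16 past the test in CAG100 against CAG0, 1 lower in CAA/G105 and 1 each way between the repeats. Both measured members of the list of male-specific transcripts passed as higher in CAG100 than in CAG0 in these female brains. Of them, msl-2 read 10.91 to 11.17 on the CAG0 arrays, so its transcript was not limited to males. For msl-2, a dosage compensation gene (0.29 ± 0.07), the call was lost with scores of muscle, fat body and gland genes as covariates (adjusted p = 0.0603, over a range of 0.00566 to 0.0603 across alternatives). The larger change was in the testis tubulin gene betaTub85D (1.51 ± 0.19), which was also higher in CAG100 than in CAA/G105 (1.09 ± 0.19). Ecdysone and juvenile hormone genes had 1 of 16 lower in CAA/G105 and none in CAG100. None of the 3 olfactory, 3 cuticle and 6 retrocerebral gland genes or the 1 histone gene measured passed in any comparison.

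With the arrays split between genotypes in other ways, as many changed probe sets as in the real grouping appeared in 1 of 35 splits of CAG100 against CAG0, the real one (1639, highest other 1), in 1 of 35 of CAA/G105 against CAG0 (1184, highest other 1) and in 1 of 35 of CAG100 against CAA/G105 (1869, highest other 8). For the 1129 probe sets of the exclusion it was 1 of 100 splits (highest other 803), and for the 806 that CAG100 changed against both others 1 of 100 (highest other 567). Chance as the source of these counts is argued against only at the level of 1 of 35 and 1 of 100. Those are the smallest shares that these splits can give. For the number of gene lists chance stays open: 27 of 35 splits gave at least the real 4 lists (highest other 14), 31 of 35 at least 3 (highest other 11), and 13 of 35 at least 7 (highest other 11).

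The X chromosome had the lowest share of changed genes in each comparison, 14.8%, 8.11% and 12.5%, and the highest share on a long arm was 26.6%, on 3L in CAG100 against CAA/G105. Among 15 comparisons of RNA quality and hybridisation controls none passed (lowest adjusted p = 0.0857). A single comparison at the smallest p possible with 4 arrays per genotype could not pass this adjustment. The lack of a pass therefore does not show that RNA quality was equal. The difference between 3' and 5' signal of eIF-4a was 1.95 ± 0.09 in CAG100, 2.17 ± 0.08 in CAA/G105 and 2.29 ± 0.06 in CAG0 (exact permutation p = 0.0286 for CAG100 against each, that smallest p). The same p was reached by that difference for GAPDH, which was 1.77 ± 0.03 in CAA/G105 against 1.72 ± 0.02 in CAG100 and 1.68 ± 0.04 in CAG0, and by the hybridisation control bioB, at 10.6 ± 0.07 in CAG100 against 10.4 ± 0.11 in CAG0.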
